A study of Arabidopsis thaliana with 16 samples.

How the data were processed

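Affymetrix ATH1 arrays measured transcript levels in 4 lengthwise zones of Arabidopsis thaliana (Columbia) roots after 1 h on standard medium or on medium with 140 mM NaCl. Each zone and medium had 2 arrays, 16 in all. Per the labels, RNA from about 15 pooled sections per replicate was amplified with a two-cycle protocol and labelled with biotin, and MAS 5 gave 1 signal per probe set. The deposited values are signal intensities (unit: intensity) on a linear scale, from 0.022971 to 19029. In each of the 16 arrays the mean after trimming 2% at each end lay between 250.02 and 250.03, the mark of a common scaling by the authors; no other normalization between arrays was seen. Detection calls, scanner settings and processing dates were not given, so no batch could be examined.

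The table held 22810 probe sets in 16 columns. The 64 control probe sets were left out of the tests. A probe set was tested where at least 2 of the 16 arrays exceeded the 40th percentile of all values, a signal of 41.357, which left 17099. Between 56.1% and 63.4% of the probe sets of an array lay above that level. Signals were analysed as log2(signal + 16) without further normalization. The probe table named 1 gene for 9611 of the tested probe sets and several for 337. It listed no gene for the other 7151, which were tested and counted but are unnamed here. A reference annotation was used for names only.

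One linear model with a mean for each of the 8 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean), giving 8 residual and 8.61 prior degrees of freedom. The contrasts were NaCl minus standard in each zone, the mean of these 4 contrasts, and each standard zone minus the mean of the other standard zones. Moderated F tests with 3 numerator degrees of freedom compared the salt change between zones, the 4 standard groups, and the 4 NaCl groups. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 17099 probe sets, with a threshold of 0.05. The labels do not say whether the replicates came from separate cultures; if they did not, the p-values measure the spread between these samples only. The number of arrays limits the precision: the median standard error of a log2 change was 0.21 within a zone and 0.11 averaged over the zones. The procedure was tested on simulated data.

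Gene lists were tested with camera from limma at its preset correlation of 0.01 between genes, and again with the correlation estimated from the residuals. The p-values were adjusted over the lists within a contrast. The probe set with the highest mean stood for a gene with several. A list needed at least 4 measured members to be tested. Of the 28 lists fixed before the data were examined, 15 had a measured member and 5 could be tested, because many well known symbols are missing from the probe table. Of the 451 members written by name for these lists, 48 had a probe set. A list result therefore covers its measured members only, not the whole list as written. A further set of 39 lists, families and classes the probe table does name, was chosen after that table was seen and before any expression test; 38 of them could be tested.

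The genes named below were picked by a rule fixed before the data were examined, among probe sets with exactly 1 gene. It took up to 6 increases and 6 decreases per salt contrast, the largest among genes that passed the threshold and whose NaCl and standard arrays did not overlap. It also took the 10 smallest p-values for the difference between zones, the 5 largest increases per standard zone, and up to 4 members per list and comparison with the smallest p. Fewer are named in places, in the rule's order.

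The alternatives fixed at the same time were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, eBayes without the trend, each array left out in turn, models on the arrays of 1 zone or 1 medium, a replicate block, every probe set of a gene in a list, and the estimated correlation. Moving the standard reference of zones 2 and 3 along the root was added after the data were seen. The fitted slope was then taken as known, and its error was left out of the p-values. The moved reference averages arrays of neighbouring zones, which lowers its standard error. Its p-values are therefore not directly comparable with the unmoved ones. List tests with the moved reference used the preset correlation only. Where leaving out 1 array left a group with a lone array, that array was assumed to vary like those of the other groups.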

Results

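Roots grown for 5 days were moved to standard medium or to 140 mM NaCl for 1 h and then divided along their length into 4 zones, to place the early salt response within root development. Zone 1 was the outermost tip, about 150 µm long. Zone 2 took the next 200 µm or so, to about the upper end of the meristem. Zone 3 covered a further 200 to 300 µm, ending just below the first root hairs, and zone 4 the following 1000 µm or so. Each of the 8 groups held 2 arrays. The median signal of an array lay between 58.63 and 76.97, and the correlation between the 2 arrays of a group, across probe sets, between 0.9787 and 0.9855. Probe sets are not independent replicates in these correlations.

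Zone set most of the variation: the first principal component held 65.8% of the variance and ordered the arrays from tip to zone 4, and the second held 17.1%. On standard medium the mean correlation across probe sets was 0.9116 between zones 1 and 2, 0.8095 between zones 2 and 3, 0.8191 between zones 3 and 4, and 0.5383 between zones 1 and 4. Under NaCl, zone 3 lay closer to standard zone 4, with a mean correlation of 0.8721. NaCl zone 2 correlated with standard zone 3 at 0.8244. The largest separation of NaCl from standard arrays along the first component was in zone 3, at 81.8 and 85.1 against 43.6 and 51.9.

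**Figure D1:**
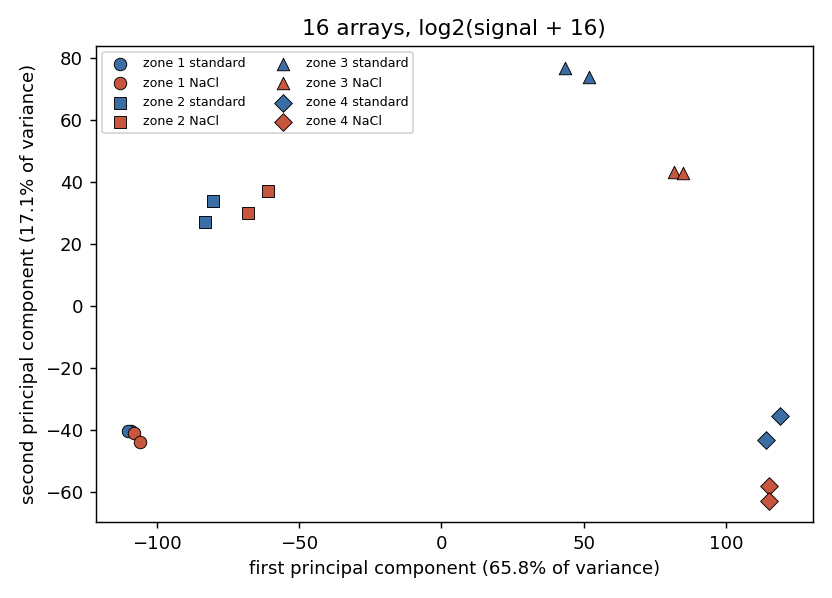
Principal components of the 16 arrays over the tested probe sets, first component on the horizontal and second on the vertical axis, with 1 point per array. The zones follow one another along the first component, and the NaCl arrays of zone 3 lie between the standard arrays of zones 3 and 4.

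On standard medium, the zones were compared to describe the stretch of development before salt. The tip was marked by AT1G50060, of the family of pathogenesis-related CAP proteins, at 9300 ± 306 (SD, n = 2) in zone 1 against 6.46, 2.14 and 1.88 in zones 2, 3 and 4. Zone 4 was marked by AT4G38080 and by genes for a GDSL lipase, AT2G23540, and a class III peroxidase, AT5G64120. The root hair expansin genes EXPA7 and EXPA18 were low in zones 1 and 2 and high in zones 3 and 4. Transcripts of the dehydrins LTI30 and COR47, proteins tied to water loss, already differed along the unsalted root.

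Of the 17099 probe sets, 13928 (81.5%) differed between the 4 standard zones. Against the mean of the other zones, 5942 were higher and 5280 lower in zone 1. In zone 2 the counts were 4613 higher and 4672 lower, in zone 3 they were 4408 and 5211, and in zone 4 they were 5448 and 5926. AT1G50060 was higher in zone 1 by 8.91 on the log2 scale (SE 0.16, adjusted p = 1.3e-16), AT3G19430 by 6.89 and AT5G60530 by 6.28. Where signals in other zones lie below the pseudocount of 16, as for AT1G50060, the size of a difference and the order of the genes depend on that constant: AT1G50060 gave 11.22 with a pseudocount of 1 and 7.12 with 64. Zone 2 was led by AT3G06460 (4.04, SE 0.19, adjusted p = 5.04e-11), the jacalin lectin gene AT1G52060 (3.81) and the thaumatin family gene AT1G73620 (3.53); the last 2 were higher still in zone 1. In zone 3, AT1G04040 was higher by 4.91 (SE 0.17, adjusted p = 4.02e-12) with a signal of 8690 ± 617, the peroxidase gene AT1G30870 by 4.70 and the lipid transfer family gene AT1G62510 by 4.66; AT1G30870 was higher still in zone 4. In zone 4, AT4G38080 was higher by 7.76 (SE 0.18, adjusted p = 3.37e-15), AT2G23540 by 7.15 and AT5G64120 by 7.09. EXPA18 was higher by 2.71 in zone 3 (adjusted p = 1.55e-09) and 4.79 in zone 4 (adjusted p = 4.83e-13), and EXPA7 by 3.68 and 4.14. LTI30 rose along the root from a signal of 321 ± 37.9 in zone 1 to 5820 ± 330 in zone 4, while COR47 was lowest in zone 2, at 392 ± 43.8.

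In each salt contrast below, every gene named from the largest changes had both NaCl arrays on the same side of both standard arrays. For changes from or to signals below the pseudocount of 16, the sizes and ranks again depend on it. In zone 1, the root tip, 1 h of salt raised transcripts of proteins tied to dehydration, among other changes. LTI30 rose from 321 ± 37.9 to 3740 ± 317 (log2 change 3.48, SE 0.11, adjusted p = 5.24e-12). LEA4-5, a late embryogenesis abundant protein gene, rose by 2.49 from a signal near background (4.39 ± 1.15), and PUB19, for a U-box ubiquitin ligase, by 2.74. The steepest increases were in AT3G55720 (4.09, SE 0.32, adjusted p = 4.69e-07) and AT5G66780 (3.68), and AT4G18425 rose by 2.52. AT2G46600, for a calcium-binding EF-hand protein, fell from 369 ± 48.5 to 24.3 ± 1.16 (-3.25, SE 0.17, adjusted p = 4.63e-09). AT1G48070 (-2.59), AT5G51310 (-2.45) and the pectin methylesterase gene AT2G47550 (-2.43) fell as well. In total 1648 probe sets (9.64%) passed, 857 higher and 791 lower, of which 612 changed more than 2-fold, and 3942 had an unadjusted p under 0.05. The balance turned to 628 higher and 947 lower with median centring, to 737 and 856 with quantile normalization, to 575 and 646 with only the 4 arrays of the zone, and to 627 and 703 with a replicate block. Leaving out an array of this zone gave 928 without standard replicate 1, 869 without standard replicate 2, 848 without NaCl replicate 1 (419 higher, 429 lower) and 1020 without NaCl replicate 2 (487 higher, 533 lower).

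In zone 2, at the end of the meristem, LTI30 and LEA4-5 again rose, and some genes for enzymes of the cell wall were among the largest changes in either direction. LTI30 rose from 886 ± 28.0 to 7870 ± 234 (3.13, SE 0.11, adjusted p = 2.1e-11) and LEA4-5 by 3.37 from 1.54 ± 0.0411, near background. AT2G43870 and AT2G43890, pectin lyase-like genes of the polygalacturonase group, rose by 3.29 (adjusted p = 4.06e-05) and 2.89 (adjusted p = 2.52e-06). AT2G41810 rose by 3.08 and AT1G20070 by 3.01. XTH16, for a xyloglucan endotransglucosylase/hydrolase, an enzyme that cuts and rejoins wall xyloglucan, fell from 438 ± 16 to 47.2 ± 8.68 (-2.85, SE 0.21, adjusted p = 1.54e-07). EXO (EXORDIUM) fell by 2.43 on the log2 scale and AT3G02640 by 2.41. In total 1949 probe sets (11.4%) passed, 1059 higher and 890 lower, with 724 beyond 2-fold. The count was 981 without standard replicate 3, 1060 without standard replicate 4, 1171 without NaCl replicate 1 and 1207 without NaCl replicate 2 of this zone, and 1297 when only the 4 arrays of the zone were used.

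Zone 3, where cells elongate before hairs emerge, had the most changed probe sets of the 4 zones. LEA4-5 rose from a signal near background, 7.12 ± 5.87, to 948 ± 102 (adjusted p = 1.01e-10). Its log2 change was 5.4 (SE 0.22), but 7.08 with a pseudocount of 1 and 3.83 with 64. The class III peroxidase gene AT5G15180 rose from 98.9 ± 15.3 to 2270 ± 390 (4.31, SE 0.21, adjusted p = 3.86e-10). AT3G53980 (4.46) and AT2G37870 (3.71), both of the lipid transfer protein family, and AT1G05340 (4.43) rose alongside. With the zone 3 reference moved toward zone 4, chosen after the data were seen, these genes rose by 2.58, 2.98 and 3.44. Among the largest falls, EXLA2, an expansin-like gene, changed by -3.31 (adjusted p = 2.52e-05), XTH16 by -3.27 (from 558 ± 64.5 to 43.7 ± 7.48), the pectin methylesterase inhibitor family gene AT5G62340 by -3.13, and AT2G47550 by -3.07 (from 1870 ± 182 to 211 ± 44.2). With the moved reference these falls were smaller, at -2.02, -2.02, -2.24 and -1.82 in the same order. AT1G22330 fell by 3.07 on one probe set and by 2.04 on its other one (adjusted p = 0.000115), and AT3G46280 changed by -2.82. In total 4420 probe sets (25.8%) passed, 2161 higher and 2259 lower. Of these, 1738 changed more than 2-fold, 1035 upward and 703 downward. The count was 2843 without standard replicate 5 and 2907 without NaCl replicate 2 of this zone. The balance turned to 1484 higher and 1359 lower without the former, 1496 and 1411 without the latter, 1714 and 1630 without standard replicate 6, and 2060 and 1969 with only the 4 arrays of the zone.

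In zone 4, among emerged hairs, LEA4-5 again rose, from 66.7 ± 5.38 to 2150 ± 60.4 (4.71, SE 0.22, adjusted p = 6.6e-10) and AT3G02480, of the same kind of protein, from 6.19 ± 2.13, near background, to 501 ± 244 (4.46, but 6.07 with a pseudocount of 1 and 2.94 with 64). AT2G41190, for an amino acid transporter, rose from 118 ± 14.2 to 2560 ± 121 (4.26, SE 0.17, adjusted p = 1.34e-10). AT2G15960 rose by 3.67 and AT5G52050, for a MATE efflux carrier, by 3.64. The pectate lyase gene AT1G11920 fell from 132 ± 17.2 to 2.35 ± 0.411 (-3.01, SE 0.30, adjusted p = 3.62e-06), AT1G44050 changed by -2.82 and AT5G24880 by -2.79. In total 2062 probe sets (12.1%) passed, 941 higher and 1121 lower, with 990 beyond 2-fold. The balance turned to 1049 higher and 952 lower with median centring, and to 606 and 590 without standard replicate 7. The count was 1196 without standard replicate 7 and 1149 without NaCl replicate 2 of this zone.

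**Figure D2:**
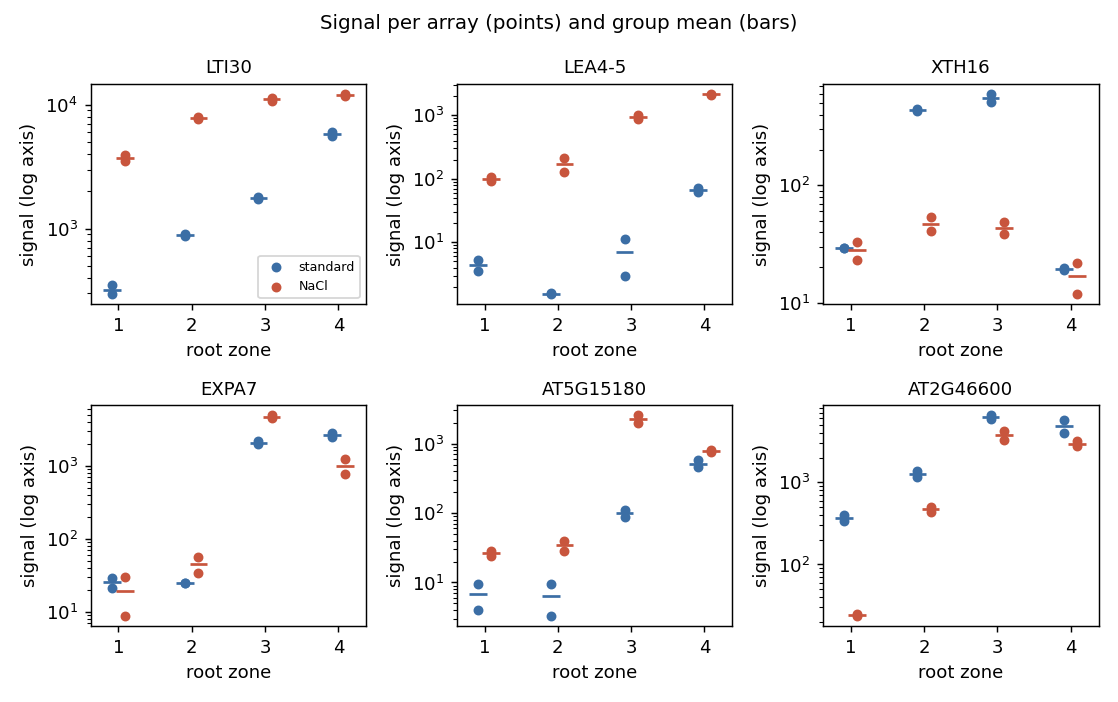
Signal (intensity, log axis) of LTI30, LEA4-5, XTH16, EXPA7, AT5G15180 and AT2G46600 in zones 1 to 4 on standard medium and on 140 mM NaCl, with 1 point per array and a bar at the mean of each group of 2. LTI30 and LEA4-5 are higher on NaCl in all 4 zones, XTH16 is lower in zones 2 and 3, and EXPA7 is higher in zone 3 and lower in zone 4.

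Averaged over the zones, LEA4-5 and LTI30 were again among the largest increases. LEA4-5 rose by 3.99 (SE 0.11, adjusted p = 1.02e-13), AT3G02480 by 2.86, SIS (Salt Induced Serine rich) by 2.61, LTI30 by 2.58 (SE 0.06, adjusted p = 8.36e-15) and PUB19 by 2.43. RTE1, which acts on ethylene receptors, rose by 0.96 (adjusted p = 6.13e-07), with 1.00, 1.00, 1.20 and 0.64 in zones 1 to 4. Its zone 4 change (adjusted p = 0.0307) was lost without standard replicate 7 (0.288), NaCl replicate 1 (0.0723) or NaCl replicate 2 (0.166) of that zone, and with only the 4 arrays of that zone (0.121). The largest decreases on average were AT1G44050 (-2.04), AT3G46280 (-1.99), the pectin methylesterase gene AT1G02810 (-1.85, SE 0.12, adjusted p = 6.39e-09) and the NRT1/PTR family transporter gene AT1G22550 (-1.75); AT3G46280 did not pass in zone 4 (-0.80, adjusted p = 0.0748). AT1G02810 fell in each zone, by -1.98, -2.04, -1.86 and -1.53. In total 5287 probe sets (30.9%) passed, 2666 higher and 2621 lower; 459 exceeded 2-fold. The balance turned to 2469 and 2774 with median centring, to 2481 and 2767 with quantile normalization, to 2471 and 2511 with the stricter filter, and without some single arrays, at most to 2394 and 2484 without zone 3 NaCl replicate 1. Probe sets that passed upward in all 4 zones numbered 155, against 0.37 for independent zones, and downward 68, against 0.36. Every pair of zones shared more increases than independence gives: 403 for zones 1 and 2 (53.1), 439 for zones 1 and 3 (108), 229 for zones 1 and 4 (47.2), 613 for zones 2 and 3 (134), 297 for zones 2 and 4 (58.3) and 542 for zones 3 and 4 (119). The zone contrasts share a single residual variance per probe set, so their calls are not independent even without a shared response. Calls in opposite directions were fewer than independence gives in every pair. They numbered 19 for zones 1 and 2 (93.6), 74 for zones 2 and 4 (118) and 145 for zones 3 and 4 (266).

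The size of the salt change was compared between zones with the interaction test, the question for which the zones were divided. AT2G41190 graded upward along the root, with log2 changes of 0.01, 1.17, 3.06 and 4.26 in zones 1 to 4 (adjusted p = 3.02e-08), and LTI30 graded downward, with 3.48, 3.13, 2.64 and 1.05 (adjusted p = 3.11e-07). LTI30 started in zone 4 from 5820 and reached 12100, where the highest signals on the NaCl arrays were 14869 and 15269. The top of the range may limit its change there, which was not tested. A second form was a peak in zone 3: AT5G55180, a glycosyl hydrolase family 17 gene, changed by -0.85, -0.70, 2.82 and 0.56 (adjusted p = 3.02e-08), and AT5G43150 had values of -0.09, -0.26, 3.16 and 0.04. UGT87A2, for a UDP-glucosyltransferase, and AT5G15180, AT2G37870 and AT1G05340 also had their largest increase in zone 3. XTH16 fell in zones 2 and 3, with -0.05 and -0.12 in zones 1 and 4 (adjusted p = 1.8e-06). Its standard signals there, 29.4 and 19.4, lay below the filter level, so a fall in those zones could hardly be measured. The peroxidase gene AT1G34510 rose in zone 3 by 2.73 and fell in zone 4, at -1.67 (adjusted p = 1.59e-06). With the zone 3 reference moved toward zone 4, chosen after the data were seen, its rise was 1.16 (adjusted p = 0.000442). By contrast, no difference between zones passed for SIS (adjusted p = 0.374) or PUB19 (0.247), although PUB19 passed without zone 4 standard replicate 7 (0.0356). In total 3127 probe sets passed, and 5580 had an unadjusted p under 0.05. Their largest change was in zone 1 for 415, zone 2 for 413, zone 3 for 1505 and zone 4 for 794. Of the 3127, 337 passed upward in one zone and downward in another.

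Zones were also compared with one another under NaCl. AT1G50060 kept a signal of 9130 ± 523 in zone 1 against 6.96, 1.77 and 2.62 further up, and AT4G38080 reached 8110 ± 1290 in zone 4. LTI30, which spanned 321 to 5820 on standard medium, spanned 3740 to 12100 under NaCl. Between the 4 NaCl groups 14052 probe sets (82.2%) differed.

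The list of dehydration proteins linked to abscisic acid, the main hormone of water stress, had 4 measured members: LTI30, LEA4-5, COR47 and COR15B. LTI30 and LEA4-5 rose in every zone, and COR47 rose in zones 2 and 3. COR15B passed in no salt contrast. In zone 1, 2 members rose and 2 did not pass (3 rose when adjusted over the list alone; camera adjusted p = 9.45e-06, and adjusted p = 0.00826 with an estimated correlation). In zone 2, 3 rose and 1 did not pass, 3 adjusted over the list alone (adjusted p = 8.25e-08, and 0.00285 with an estimated correlation). In zone 3, 3 rose and 1 did not, 3 adjusted over the list alone (1.08e-05, and 0.00856 with an estimated correlation). In zone 4, 2 rose and 2 did not, 2 adjusted over the list alone (4.87e-05, and 0.00787 with an estimated correlation). On average 3 rose and 1 did not, 3 adjusted over the list alone (1.5e-06, and 0.00529 with an estimated correlation). COR47 rose by 2.59 in zone 2 (adjusted p = 2.7e-08) and 1.38 in zone 3 (9.82e-06), with 0.11 and 0.14 in zones 1 and 4, and its change differed between zones (adjusted p = 6.77e-06).

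The root hair list had 4 measured members: EXPA7, EXPA18, XTH26 and SCN1. In zone 4 all 4 fell (4 adjusted over the list alone; camera adjusted p = 4.87e-05, and adjusted p = 0.00787 with an estimated correlation), with a median of -1.4. EXPA18 changed by -1.74 (adjusted p = 3.44e-05), EXPA7 by -1.43 (0.00113), XTH26 by -1.42 (0.00272) and SCN1 by -0.48 (0.0361). In zone 3, EXPA7 rose by 1.18 (0.00268) and EXPA18 by 1.01 (0.00235), the other 2 did not pass, 2 rose adjusted over the list alone, and the list did not pass (adjusted p = 0.119). The change differed between zones for EXPA18 (adjusted p = 7.2e-05) and EXPA7 (0.000581). In zone 1, EXPA18 fell by 0.87 (0.0166) and the list did not pass (0.258); in zone 2 no member passed (0.316), and on average 1 fell (0.529). Several of these calls rested on single arrays. The fall of EXPA18 on average lost its call without zone 2 standard replicate 3 (log2 change -0.31), zone 3 standard replicate 6 (-0.29) or zone 4 NaCl replicate 2 (-0.32). EXPA18 was lost in zone 3 without standard replicate 5 (0.0549), and there also with the standard reference moved toward zone 4 (0.53, adjusted p = 0.0622), an alternative chosen after the data were seen. It was lost in zone 1 without NaCl replicate 2 (0.214), standard replicate 1 (0.102) or standard replicate 2 (0.0619), with a pseudocount of 64 (0.13), with only the 4 arrays of the zone (0.127) and with a replicate block (0.107). In zone 4, XTH26 was lost without standard replicate 7 (0.0525) and with a pseudocount of 1 (0.221). SCN1 was lost there without standard replicate 7 (0.222), standard replicate 8 (0.0551), NaCl replicate 1 (0.17) or NaCl replicate 2 (0.0737), and with median centring (0.0705), eBayes without the trend (0.0845) or only the 4 arrays of the zone (0.108).

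Genes of wall loosening, which soften the wall during growth, had 6 measured members. In zone 4, 3 fell and 3 did not pass, 3 adjusted over the list alone (camera adjusted p = 0.00522, and adjusted p = 0.0273 with an estimated correlation), with a median of -0.59. XTH18 changed by -2.09 (adjusted p = 0.000128) and XTH19 by -1.80 (2.53e-05). Both also fell in zone 3, by -2.13 (5.09e-05) and -1.15 (0.000802), where the list did not pass (0.537). With the standard reference moved toward zone 4, chosen after the data were seen, XTH19 changed by -0.13 in zone 3 and did not pass (adjusted p = 0.688). No list call was made in zone 1 (1 rose; 0.511), zone 2 (2 rose, 3 adjusted over the list alone; 0.316) or on average (1 rose and 2 fell; 0.529).

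The list of rapid stress and touch genes passed upward in zone 4 alone among the salt contrasts, with 1 of 6 members past the threshold, the transcription factor gene WRKY6 (0.97, adjusted p = 0.00761), and 2 adjusted over the list alone. The camera adjusted p was 0.0208, lost with an estimated correlation at an adjusted p = 0.227 with an estimated correlation. The list was also lost without standard replicate 8 (0.141) or NaCl replicate 1 (0.075) of zone 4, and WRKY6 was lost without the same arrays (0.069 and 0.0684). In zone 1 (0.117) the list passed downward without zone 1 standard replicate 2 (0.00175), zone 2 standard replicate 3 (0.0342) or zone 2 standard replicate 4 (0.033). In zone 2 (0.188) it passed downward without zone 2 standard replicate 4 (0.00171), and with the standard reference moved toward zone 3 (0.0477), chosen after the data were seen. No call was made in zone 3 (0.93) or on average (0.897).

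The auxin list, with 8 measured members, passed in no salt contrast (adjusted p = 0.251, 0.843, 0.334 and 0.664 in zones 1 to 4, and 0.976 on average). Its members passed singly: 1 fell in zone 1, 1 fell in zone 2, 3 rose and 1 fell in zone 3, and 1 rose and 1 fell in zone 4, with the same counts adjusted over the list alone. GH3.1, of the family of enzymes that join auxin to amino acids, fell in zone 3 (-1.66, adjusted p = 0.00144). GH3.3 rose in zone 3 (1.43, 0.00712) from a signal of 6.36 ± 5.03, and fell in zone 4 (-1.85, 0.0021). In zone 3 the call for GH3.3 was lost without standard replicate 5 (0.0782) or NaCl replicate 1 (0.082), with a pseudocount of 64 (0.0666), and with the standard reference moved toward zone 4 (-0.01, 0.984). In zone 4 it was lost without standard replicate 8 (0.0514) and with a pseudocount of 1 (0.122).

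Between standard zones, the root hair list was lower in zone 1 (4 lower; camera adjusted p = 0.00612) and zone 2 (3 lower; 0.0129) and higher in zone 4 (4 higher; 0.00883). These counts were the same adjusted over the list alone. In zone 3 it did not pass (3 higher, 1 lower; 0.0712), but did without standard replicate 5 of that zone (0.0389). The dehydration list was higher in zone 4 (3 higher; 0.0293) and lower in zone 2 (3 lower, 1 higher; 0.0465), and the auxin list was lower in zone 2 (5 lower, 6 adjusted over the list alone; 0.0465). None of these 6 calls held with an estimated correlation: adjusted p = 0.0558, 0.0779 and 0.0656 with an estimated correlation for the root hair list in zones 1, 2 and 4, 0.0987 and 0.107 for the dehydration list in zones 4 and 2, and 0.105 for the auxin list. The zone 2 call of the dehydration list was lost without zone 3 standard replicate 6 (0.0537), zone 4 standard replicate 7 (0.0527), either zone 1 NaCl array (0.0505 and 0.0504), either zone 3 NaCl array (0.0504 for both) or either zone 4 NaCl array (0.0531 and 0.0532). It was also lost with a pseudocount of 64 (0.0804), no filter (0.061) and eBayes without the trend (0.0873). The auxin call was lost without zone 1 NaCl replicate 1 (0.0505) or 2 (0.0504), a pseudocount of 64 (0.0507) and the stricter filter (0.0662). Over the 9 contrasts and 5 lists, 14 of 45 tests passed, 7 of them with an estimated correlation. The difference between zones was tested for single genes, not for lists. Of the 10 lists with too few members to test, the cell cycle list had 3, all higher in standard zone 1; under salt 1 fell in zone 1, 2 fell in zone 2, and none passed in zones 3 or 4.

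Among the families the probe table does name, genes for cytosolic ribosomal proteins, which build the machinery of protein synthesis, fell in zone 3. Of 117 measured, 90 passed downward there (100 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 7.65e-25, lost at an adjusted p = 0.148 with an estimated correlation). AT5G15520 changed by -1.20 (adjusted p = 2.37e-06) and AT3G16080 by -0.97 (7.1e-06) there. In zone 1, 5 fell and in zone 2, 8 fell (0.0101 and 0.00568, lost at 0.677 and 0.535 with an estimated correlation), the former also without zone 1 standard replicate 2 (0.0773) and with quantile normalization (0.458), the latter also with the standard reference moved toward zone 3 (0.997). With the reference of zone 3 moved toward zone 4, the zone 3 median was -0.23 (2.63e-07). In zone 4, 3 fell and the list did not pass (0.413), except without NaCl replicate 1 (0.0224). Replication-type core histones, 8 measured, fell for 5 members in zone 1, 5 in zone 2 and 6 in zone 3 (5, 6 and 6 adjusted over the list alone; 0.0035, 0.000554 and 0.000901, lost at 0.423, 0.23 and 0.151 with an estimated correlation). The measured members were histone H2B genes only, so the list says nothing of the other core histones. One of them, HTB4, changed by -1.04, -0.74 and -1.20 in zones 1, 2 and 3. Autophagy genes of the ATG family rose: 7 of 8 in zone 3 (8 adjusted over the list alone; 5.46e-06, lost at 0.148 with an estimated correlation), among them ATG8E (2.14, adjusted p = 1e-06) and ATG8H (1.53, 8.47e-07), and none passed in zone 4 (0.318). All measured members but ATG3 were ATG8 genes. On standard medium the median of the family was higher in zone 4 than in the other zones (1.7), toward which NaCl zone 3 lay. No test of this family passed with an estimated correlation. With the zone 3 reference moved toward zone 4, chosen after the data were seen, its median was 0.65 (0.000166), with ATG8E at 1.61 and ATG8H at 1.09. In zones 1 and 2, 3 rose in each (4 adjusted over the list alone; 0.0254 and 0.00454, lost at 0.597 and 0.366 with an estimated correlation), the former also lost without standard replicate 1 (0.0647) or NaCl replicate 2 (0.051) of zone 1, and with eBayes without the trend (0.0558). Late embryogenesis abundant and dehydrin genes, 16 measured and partly shared with the dehydration list, rose for 6 members in zone 2 (8 adjusted over the list alone; 2.71e-06, and 0.0158 with an estimated correlation) and 9 on average (9 adjusted over the list alone; 3.89e-06, and 0.02 with an estimated correlation). In zones 1 and 3, 4 and 5 rose, and in zone 4, 6 rose and 1 fell (0.00128, 0.000313 and 0.000126, lost at 0.119, 0.0737 and 0.0534 with an estimated correlation). The dehydrin family gene AT4G38410 rose by 2.28 in zone 1, 2.47 in zone 2 and 1.31 in zone 4, with -0.11 in zone 3, a difference between zones (adjusted p = 4.15e-05).

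XTH and extensin genes were the wall families examined next. Of 8 XTH genes, which share members with the hair and wall lists, 5 fell in zone 3 and 5 in zone 4 (5 and 6 adjusted over the list alone; camera adjusted p = 0.023 and 4.35e-05, lost at 0.196 and 0.0534 with an estimated correlation). The zone 3 call was also lost without standard replicate 6 (0.0535), with a pseudocount of 1 (0.0583) and with the stricter filter (0.122). XTH21 changed by -2.22 in zone 3 (adjusted p = 8.45e-05) and -2.43 in zone 4 (7.83e-05). Of 8 extensins, structural wall glycoproteins, 5 fell in zone 4 (7 adjusted over the list alone; 0.000126, lost at 0.27 with an estimated correlation), with a median of -0.87. AT4G08410 changed by -1.50 (adjusted p = 0.000755), on a probe set that can match related transcripts. The peroxidase gene AT3G49960, high in zones 3 and 4, fell in zone 4 alone among the zones, at -1.97 (1.86e-06; difference between zones 7.2e-05). No list median that passed changed its sign under quantile normalization or median centring.

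**Figure D3:**
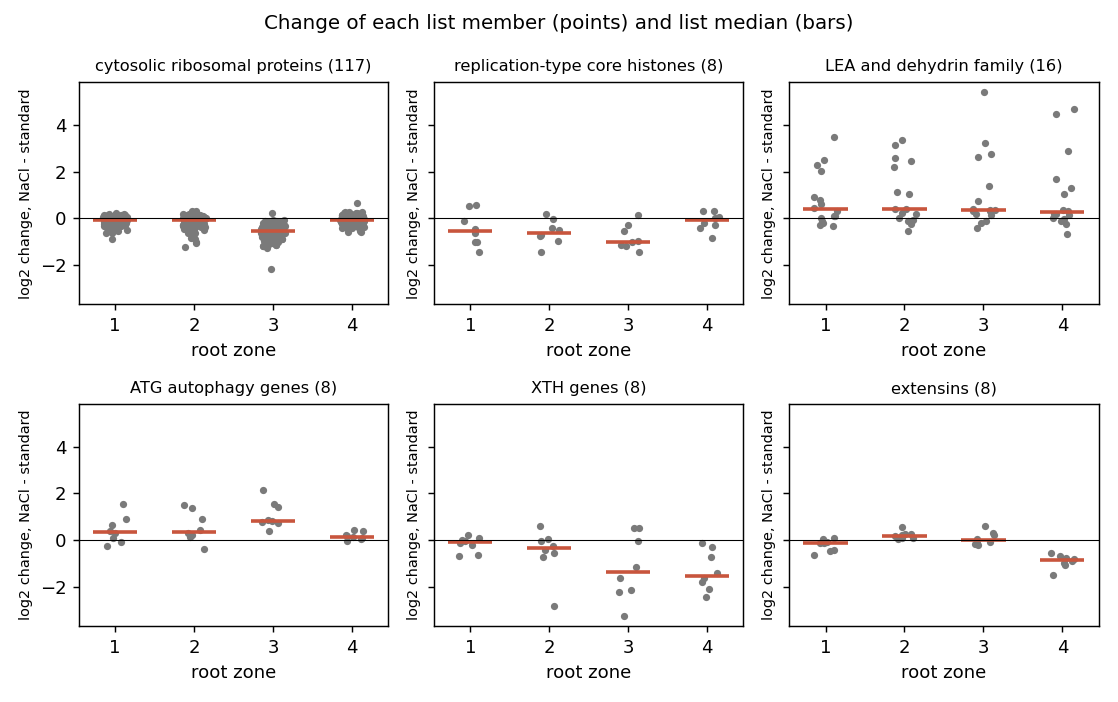
Log2 change (NaCl minus standard) of the measured members of 6 gene families in zones 1 to 4, with 1 point per gene and a bar at the median. Ribosomal protein genes lie lowest in zone 3 (median -0.57), autophagy genes highest in zone 3 (0.82), and extensins lowest in zone 4 (-0.87). The core histones shown are H2B genes, and the autophagy genes are ATG8 genes and ATG3. No median of a list that passed changes its sign with another scaling.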

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

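The share of graded genes moving toward their zone 4 level, the slope in zone 1, the moved reference and the comparison of control ratios within zone 3 are tests that were chosen after the results they measure were seen; the other tests here were set beforehand. The comparison within zone 3 replaced one with all arrays, set beforehand, whose bound of 3.97 came from zone 1 and so could not decide. For the ratios of observed to predicted change, the demand that every single-array ratio also exceed 2 before older tissue is excluded was added after the ratios were seen; without it, older tissue would be excluded for the root hair list in zone 3. What set these results apart was a difference between the zones in the salt change, by the interaction test, or a change in the control probe sets, which no comparison uses.

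The first pattern is that zone 3 under NaCl lay closer to zone 4 than zone 3 on standard medium did. Older tissue in the NaCl sections of zone 3, from a shift in where the cuts fell, stays open: among graded probe sets not called for salt in zones 1, 2 and 4, the smaller share moving toward the zone 4 level was 77.9%, but a salt response in zone 3 would give such a share too. A salt response common to all zones is weakly argued against by zone 1. Its slope on the step from zone 3 to zone 4 was 0.024, against 0.309 in zone 3 (0.278 to 0.343 with single arrays). Genes near background in zone 1 have little room to fall there, which can lower that slope. On that same step zone 2 had a slope of 0.045 (0.021 to 0.068), also far under that of zone 3. Along its own next step zone 2 moved by 0.111 (0.072 to 0.149) and zone 1 by 0.044 (0.022 to 0.063). A response of zones 2 and 3, each along its own next step, stays open. Array scaling is argued against by a zone 3 slope of 0.304 after quantile normalization. A salt response of zone 3, such as earlier maturation within 1 h, stays open as untested, since no section was measured for its position.

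The second pattern is the lower level of ribosomal protein transcripts in zone 3 under NaCl, with a median of -0.557 over 117 genes, a mean of medians taken against each standard array singly (-0.57 in the linear model). A shift along the slope of the first pattern, the stand-in for older tissue, gives -0.323. The observed fall was 1.72 times that (1.38 to 2.15 over single arrays). With the reference moved by the slope the median was -0.23 (camera adjusted p = 2.63e-07, at the preset correlation only). The unmoved call was lost with an estimated correlation. The slope was fitted on the same zone 3 arrays, holds any salt response too, and is 1 log2 value for all genes, whereas mixed tissues add signals on the linear scale. How much of the fall older tissue may explain stays open. Scaling is argued against by a ratio of 1 between the medians after quantile normalization and with the deposited scaling. Poorer RNA stays open: 0 of the 3 control transcripts had a higher 3' to 5' ratio in both NaCl arrays of zone 3 than in both standard arrays, and actin (4.17 and 4.22 against 4.76 and 4.38) and ubiquitin (1.32 and 1.31 against 1.78 and 1.73) were lower, the opposite of what poorer RNA predicts, but the controls for both changed with salt there, and GAPDH (1.97 and 1.72 against 1.72 and 1.97) did not separate the arrays. A salt effect on these genes in zone 3 remains an open biological explanation.

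The third pattern is that EXPA7 and EXPA18 rose in zone 3, where the root hair list did not pass (0.119), and that all 4 genes of the list fell in zone 4. In zone 3 the observed median of the list, 0.598 by the same averaging, was 2.04 times the 0.294 that a shift along the slope gives (1.3 to 3.03 over single arrays). The test has the same limits as for the ribosomal genes. It leaves older tissue open for that zone and says nothing of the fall in zone 4. EXPA7, at 4780 ± 272 on NaCl, exceeded standard zones 3 and 4 (2100 and 2670), which a plain mix of these tissues would not give, and kept its call with the reference moved (1.07, adjusted p = 0.00277), but EXPA18 lay between them (2700 against 1360 and 3950) and a peak of EXPA7 between the sections was not measured. Scaling is argued against, since the difference between the zones kept at least 0.972 of its size under quantile normalization and median centring. A salt response of hair genes that differs by zone stays open as a biological explanation.

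For the average over the zones, 1 of 100 splits of the arrays within zones, the real one, called as many probe sets: 5287. The highest other split called 2764 and the median other split 0. Splits unrelated to medium leave the salt change in the residual spread, which lowers their counts, so they are a weak test of chance. A culture or batch difference that follows medium is not tested by the splits. Some of the other splits overlap the real grouping in part.

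The salt change differed between zones for 3127 probe sets. Among the named genes the adjusted p of that difference was 3.02e-08 for AT2G41190 and AT5G55180, 3.11e-07 for LTI30, 8.77e-07 for AT1G05340, AT5G43150 and UGT87A2, 1.13e-06 for AT2G37870, 1.55e-06 for AT5G15180, 1.59e-06 for AT1G34510, 1.8e-06 for XTH16, 5.96e-06 for AT3G55720 and 6.77e-06 for COR47. It was 1.06e-05 for AT2G46600, 1.42e-05 for AT5G52050, 3.17e-05 for AT3G53980, 4.14e-05 for LEA4-5, 4.15e-05 for AT4G38410, 4.9e-05 for AT2G15960, 5.53e-05 for AT5G24880, 7.2e-05 for AT3G49960 and EXPA18, 9.83e-05 for AT1G48070 and 9.85e-05 for AT3G02640. Values of 0.000125 for AT1G11920, 0.000134 for AT1G20070, 0.000291 for EXLA2, 0.00033 for ATG8H, 0.00035 for AT2G43890, 0.000382 for AT2G43870, 0.000436 for AT2G47550, 0.000467 for AT5G62340, 0.000478 for AT4G18425, 0.000581 for EXPA7, 0.000654 for AT2G41810 and 0.000765 for ATG8E followed. Then came 0.0011 for EXO, 0.00141 for AT5G66780, 0.00169 for GH3.3, 0.00176 for AT3G02480, 0.00244 for XTH21, 0.0025 for AT3G16080, 0.00333 for XTH19, 0.00431 for AT5G15520, 0.00682 for AT1G22550, 0.00815 for XTH18, 0.00823 for AT1G22330, 0.00911 for AT3G46280 and 0.00927 for HTB4. The weakest were 0.011 for AT4G08410, 0.0189 for AT5G51310, 0.0235 for XTH26, 0.0344 for AT5G64120, 0.0348 for GH3.1, 0.0427 for SCN1 and 0.0435 for AT1G44050.

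For a gene that falls, a standard signal below the filter level of 41.357 in some zones, as for XTH16 in zones 1 and 4, leaves little room for a fall there, so part of such a difference reflects where the gene is expressed.

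Of these differences, 4 were lost without single arrays. AT4G08410 was lost without zone 4 standard replicate 8 (0.0693) or zone 4 NaCl replicate 2 (0.0695), and XTH26 without zone 4 standard replicate 7 (0.133), zone 4 NaCl replicate 1 (0.0945) or zone 4 NaCl replicate 2 (0.0545). GH3.1 was lost without zone 3 standard replicate 5 (0.0668), zone 3 standard replicate 6 (0.147), zone 3 NaCl replicate 2 (0.174), zone 4 standard replicate 7 (0.0553), zone 4 standard replicate 8 (0.0574) or zone 4 NaCl replicate 2 (0.0636). SCN1 was lost without zone 2 standard replicate 3 (0.0772), zone 2 standard replicate 4 (0.0563), zone 2 NaCl replicate 2 (0.063), zone 3 standard replicate 5 (0.0851), zone 3 NaCl replicate 1 (0.069), zone 3 NaCl replicate 2 (0.0797), zone 4 standard replicate 7 (0.154), zone 4 standard replicate 8 (0.0564), zone 4 NaCl replicate 1 (0.138) or zone 4 NaCl replicate 2 (0.0618). With other settings, a pseudocount of 1 ended the difference for GH3.1 (0.0864), XTH18 (0.162), XTH26 (0.369) and SCN1 (0.0538), no filter for GH3.1 (0.0555) and SCN1 (0.0563), median centring for SCN1 (0.0823), and eBayes without the trend for SCN1 (0.108) and HTB4 (0.0529).

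Of the 64 control probe sets, 4 changed under NaCl in zone 1, 3 in zone 2, 6 in zone 3 and 2 in zone 4. In zone 1 these included a bacterial spike-in control for bioC, at -0.47 (adjusted p = 0.0276), which is not a plant transcript, so that difference is technical. The 3 others there were 5' end controls of actin (0.77) and ubiquitin (0.51 and 0.48), which rose. The log2 3' to 5' ratios of actin, GAPDH and ubiquitin were all lower in both zone 1 NaCl arrays than in both standard ones. Actin had 4.04 and 4.11 against 4.84 and 5.07. GAPDH had 2.01 and 1.92 against 2.09 and 2.58, and ubiquitin 2.33 and 2.44 against 2.45 and 2.85. How far this bears on the zone 1 salt changes was not tested. The largest change of a control probe set was in a ubiquitin control for the middle of the transcript, at 1.3 in zone 3. A ubiquitin control for the 5' end rose by 0.48, 0.57, 0.70 and 0.70 in zones 1 to 4, and in zone 3 actin controls changed by -0.55, -0.49 and -0.50, while the mean log2 ratio of 3' to 5' signals was 2.81 and 2.84 on NaCl against 3.26 and 3.08 on standard medium; none of the control directions changed under quantile normalization or median centring.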

How the results depend on the processing

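The moved standard reference was added after the data were seen; the other alternatives were set before the data were examined. Over the 7 to 9 other settings tried per result, the counts ran from 1221 to 1806 in zone 1 (1648 in the analysis reported), 1297 to 1996 in zone 2 (1949), 3933 to 4603 in zone 3 (4420), 1508 to 2494 in zone 4 (2062), 4789 to 5718 on average (5287) and 2301 to 3842 for the difference between zones (3127). They ran from 11796 to 14341 between standard zones (13928) and 11882 to 14438 between NaCl zones (14052). The zone 2 count of 1297, from the 4 arrays of that zone alone, had 2 residual degrees of freedom in place of 8. List calls (14) numbered 6 with the stricter filter, which left 4 lists and 36 tests in place of 5 and 45, and 7 with an estimated correlation. Leaving out each array in turn gave 848 to 1681 in zone 1, 981 to 1969 in zone 2, 2843 to 4455 in zone 3, 1149 to 2104 in zone 4, 4669 to 5151 on average, 2331 to 3032 for the difference between zones, 13357 to 13952 and 13399 to 14045 between standard and NaCl zones, and 12 to 16 list calls; the cause was not tested. The lowest count of each zone came without an array of that zone, where the lone array left in its group widens the standard error. With the standard reference moved toward the next zone, zone 2 gave 1844 and zone 3 gave 3623, and the rise of GH3.3 in zone 3 was removed, from 1.43 to -0.01 (adjusted p = 0.984), since its standard signal is far higher in zone 4. In zone 3, XTH19 went from -1.15 to -0.13 (0.688, lost) and EXPA18 from 1.01 to 0.53 (0.0622, lost), while XTH26 at -1.06 (0.00614) and SCN1 at 0.43 (0.0228) gained a call. In zone 2, AT5G64120 at 0.61 was lost (0.0655) and XTH21 at -1.05 gained a call (0.039). Such gained calls need care, since the moved contrast has a smaller standard error and takes the slope as known. List calls numbered 15 with the zone 2 reference moved and 14 with that of zone 3. The replicate numbers are shared only by the zone 1 groups and by the NaCl groups. As a block they gave 1330 in zone 1 and 13754 between NaCl zones, and the calls of EXPA18 (0.107) and ATG8E (0.0697) in zone 1 were lost; the pairing check gave r = 0.03 in zone 1 and -0.011 to 0.057 between NaCl groups. For the 72 named genes, 280 values were recomputed 6734 times: 6572 kept their side of the threshold, 137 lost a call and 24 gained one. The remaining 1, GH3.3, lost its call with a change of sign. Some of the 6572 changed sign with no call in either setting, such as EXPA7 in zone 2 with the moved reference (0.55 to -0.08). Of the 6734, 4480 left out an array, often one of a zone that the value does not compare. Many of the genes were also picked for large changes or small p-values, so the 6572 is a weak measure of stability. Signal over background limits genes near the pseudocount of 16, whose log2 changes shrink as it grows. In simulated data with 17099 probe sets, 60% of changes of size 1 and 98% of size 2 were called in zone 1.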

Other observations

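The moved standard reference is the only one of the tests here chosen after the results were seen; the families come from the set chosen once the probe table was known. Of 13 mitochondrial-encoded transcripts, 3 fell in zone 1 (6 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.000707, lost at an adjusted p = 0.492 with an estimated correlation). Of 68 plastid-encoded transcripts, 1 fell in zone 1 and 10 in zone 2, the same counts adjusted over the list alone (0.000431 and 0.000554, lost at 0.677 and 0.535 with an estimated correlation). The plastid call in zone 1 was lost, with the direction turned, without NaCl replicate 1 of that zone (0.912). On average 5 mitochondrial (0.02) and 21 plastid transcripts (0.000909) fell, calls lost at 0.537 and 0.666 with an estimated correlation and both lost without zone 1 NaCl replicate 1 (0.066 for both). The mitochondrial one was also lost with the stricter filter (0.105).

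Nuclear genes of photosynthesis, which plastids need in green tissue, rose in zone 3 for 7 of 16 members (8 adjusted over the list alone; median 0.61, adjusted p = 0.00763, lost at 0.324 with an estimated correlation, at 0.0743 without zone 3 NaCl replicate 2, and at 0.23 with the stricter filter). Named cell division and replication genes, higher in standard zone 1 for 20 of 24, fell for 4 members in zone 2 (6 adjusted over the list alone; 0.0133, lost at 0.482 with an estimated correlation, at 0.217 without zone 2 NaCl replicate 1, and at 0.273 with the standard reference moved toward zone 3). Genes of the endoplasmic reticulum stress response fell for 3 of 13 in zone 2 (7 adjusted over the list alone; 0.0267, lost at 0.283 with an estimated correlation), a call lost without zone 2 standard replicate 4 (0.127) or zone 2 NaCl replicate 1 (0.0601). Small heat shock proteins and co-chaperones fell for 2 of 14 in zone 2 (3 adjusted over the list alone; 0.016, lost at 0.492 with an estimated correlation), a call lost without the same arrays (0.127 and 0.173). Class III peroxidases, 42 measured, were lower in standard zone 1 for 31 members and higher in zone 4 for 30. Under NaCl 6 fell and 1 rose in zone 1 (6 and 1 adjusted over the list alone; 0.0115, lost at 0.423 with an estimated correlation, and at 0.111 without zone 1 standard replicate 1). Over all 38 tested families and 9 contrasts, 81 of 342 tests passed, 2 of them with an estimated correlation.

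The mean log2 ratio of 3' to 5' control signals lay between 2.53 and 3.97 over the 16 arrays. Salt changes in neighbouring and distant zones were related across genes, with r from 0.25 (zones 1 and 4) to 0.50 (zones 1 and 2); genes are not independent replicates.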
